A study of Homo sapiens with 2 samples.

How the data were processed

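RNA from 2 HepG2 sublines, 1 infected with a control lentivirus and 1 with a lentivirus for SOX9, gave 1 library each. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed and messenger RNA was purified and sequenced on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA 1.4 and HISAT2 2.0.5 without a role. The read counter, its use of strand and its treatment of reads that match several places are not given in the sources used here.

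The authors deposited a single table of 63009 rows with read counts, FPKM and their own comparison. The deposited counts are whole numbers per gene, not normalized, per the file headers and the values. Reads that match several places could be split or dropped among copies of a gene by such counting, and reads over overlapping genes could be assigned to either. The deposited FPKM values are, from their proportions, counts per kilobase of the table's gene length and per 1000000 of a rescaled library size, at 0.990 times the total in the control and 1.01 times in the library labelled SOX9. The deposited log2 fold changes are of the SOX9 column over the control column, per the file headers. The deposited p-values and adjusted p-values belong to the authors' comparison of 1 library with 1 library, and the tool is not given in the sources used here. A check with edgeR gave the same p and log2 fold change within 1e-06 for all 23533 rows, with its exact test, TMM scaling and a dispersion of 0.04. Preset dispersions of 0.01 and 0.16 gave the same p for 3209 and 3153 rows.

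The submitters' processing notes name the build hg18, but the coordinates are those of GRCh38. Of 55298 rows whose identifier is in GENCODE 29, 93.2% had the same start and end there. Coordinates are printed as the table gives them. Rows with no Ensembl identifier numbered 252 and took 0.247% of counts in the control and 0.243% in the library labelled SOX9. They were kept in the library totals. Rows on alternate sequences of the genome numbered 3983 and took 0.230% and 0.236%. A further 2 columns of per-sample values were not used.

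Total counts were 16467299 in the control and 16771930 in the library labelled SOX9, with 23530 and 23901 genes having a count. The 10 most abundant genes took 12.1% and 9.52% of counts. Counts were scaled with TMM in edgeR 4.0.16 (R 4.3.3) to CPM, and log2 ratios used a pseudocount of 0.5 CPM. Genes with a mean of at least 1 CPM over both libraries were examined, 13842 in all, of which 11833 were protein coding. Printed ratios are of CPM without the pseudocount. Their 95% intervals are exact Clopper-Pearson intervals of the share of counts in the library labelled SOX9, converted to a ratio. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, not the spread between cultures. A gene with 0 counts in a library kept its 0, with the pseudocount added, in the log2 ratios, the 2-fold counts and the list medians. For a named gene of this kind a bound on the ratio was also taken, with a floor of 3 counts in that library.

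With 1 library per group no test of the conditions is given as a result. The p-values of the edgeR check served only to find how the deposited p-values were made. Genes were counted by a fixed rule of size, a log2 ratio of at least 1 or at most −1. Each of 48 gene lists, together holding 1089 distinct symbols and written before the data were examined, was summarised by the median log2 ratio of its measured genes. For lists with at least 3 measured genes the percentile of that median was taken among 10000 random lists with as many genes from the same of 20 bins of mean expression. Where a symbol had several rows, the row with the highest mean was used. Some genes stand in several lists.

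The genes named in the text follow a rule fixed before the data were examined. SOX9 came before all others, then the 12 protein-coding rows with the highest and the 12 with the lowest log2 ratio among those with a mean of at least 5 CPM. Up to 4 members with the largest absolute log2 ratio in each described list were eligible, and ALB, AFP, HNF4A, KRT19, COL2A1, MYC and ACTB were given whatever their values. Markers of other cells are named with their levels. Some genes eligible under this rule are not reported here.

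The method was tested on simulated counts with the real means and library sizes, for the comparison of the 2 libraries. These counts were drawn independently for each gene with counting error only, so the simulation does not cover the spread between cultures. Among 13842 genes, of those with a true 3-fold difference 96% were counted as at least 2-fold, of those with 4-fold and 8-fold differences 100%, and of those with 1.5-fold differences 0%. Intervals held the true ratio for 94% of 200 genes with a simulated difference. Of 200 random lists drawn from 13855 genes, 6.5% fell outside percentiles 2.5 to 97.5.

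Alternatives fixed before the data were examined were scaling by total counts, DESeq2 1.42.0 size factors or the upper quartile, no minimum level or a minimum mean of 5 CPM, pseudocounts of 0.1 and 2 CPM, FPKM in place of counts with a minimum mean of 1 FPKM and a pseudocount of 0.1 FPKM, and protein-coding genes only. Summing rows with the same symbol and TMM scaling without the 50 most abundant genes were added after the data were seen. Calculations other than scaling used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.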

Results

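Polyadenylated RNA was sequenced from 2 stable sublines of HepG2, a human hepatoma cell line that keeps many hepatocyte functions. Each subline came from infection with a lentivirus, a virus that integrates its cargo into the genome, and from selection with puromycin. The virus carried SOX9 in the subline labelled SOX9, and the control subline received a control virus. SOX9 is a transcription factor of cartilage, bile ducts and several stem cell compartments. The question was which genes differ in HepG2 when SOX9 is expressed ectopically. Each group held 1 library, so no difference below has a replicate check, and no test that covers differences between cultures was possible. The total count was 16467299 in the control library and 16771930 in the library labelled SOX9. A count of 3, the floor used only to bound the ratio of a gene not detected, equalled 0.186 counts per 1000000 (CPM) in the control and 0.176 CPM in the library labelled SOX9. Ratios are given as the library labelled SOX9 over the control, with exact 95% intervals that cover counting error only.

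SOX9 itself was lower in the library labelled SOX9. The gene (ENSG00000125398, chromosome 17, 72121020 to 72126420, GRCh38 coordinates, protein coding) had 4739 counts, or 293 CPM, in the control library and 3935 counts, or 230 CPM, in the library labelled SOX9. The ratio was 0.786 (95% interval 0.753 to 0.820), which is a log2 ratio of −0.35. The FPKM values of the authors' deposited table for SOX9 were 73.9 in the control and 59.0 in the library labelled SOX9. The SOX9 level therefore went against the label, and each direction below refers to the library labelled SOX9 whatever that library holds. The antisense transcript SOX9-AS1, which overlaps SOX9, had 32 counts in the control and 16 in the library labelled SOX9, a ratio of 0.473 (0.242 to 0.888). Reads of the overlapping pair cannot be told apart where the counting ignored strand, and whether it did is not given in the sources used here.

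**Figure D1:**
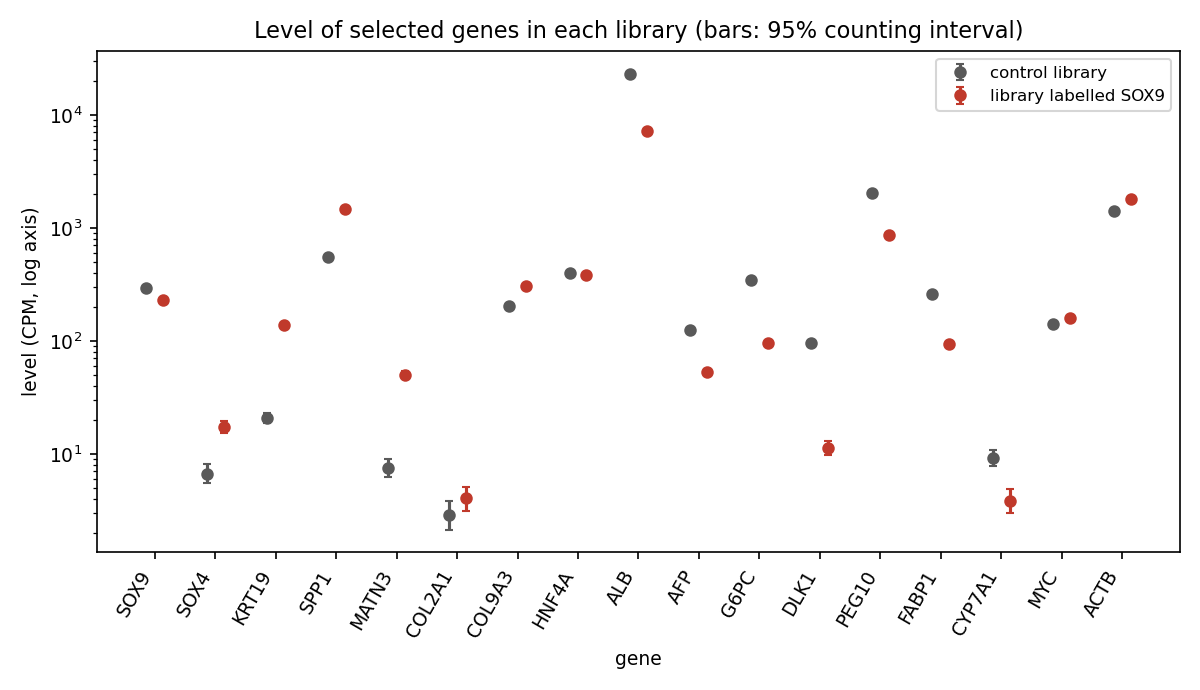
Level of 17 genes in the control library (grey) and the library labelled SOX9 (red), in CPM on a log axis, with exact 95% intervals for counting error. SOX9 stands at 293 CPM in the control and 230 CPM in the library labelled SOX9, while KRT19 stands at 20.8 and 137 CPM.

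Among 13842 genes with a mean of at least 1 CPM, 209 (1.51%) were at least 2-fold higher in the library labelled SOX9 and 245 (1.77%) at least 2-fold lower, in a library where SOX9 read lower. Of these, 38 were at least 4-fold higher and 22 at least 4-fold lower. The interval of the ratio excluded 1 for all 454, which the minimum level and the 2-fold rule bring about by construction. The middle 50% of genes had log2 ratios from −0.19 to 0.17, around a median of 0.0025. Counting error alone gave 1.59 genes at least 2-fold higher and 1.16 lower on average in simulated pairs of libraries. The numbers depend on the treatment of low genes, since a pseudocount of 2 CPM left 103 higher and 102 lower genes and a minimum mean of 5 CPM left 86 and 106. With no minimum the higher genes numbered 324 and the lower genes 352.

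Among protein-coding genes with a mean of at least 5 CPM, GAS7, a protein of the cytoskeleton, had the highest log2 ratio. It had 3 counts in the control and 226 in the library labelled SOX9. Its ratio was 71.3, with a wide interval of 24.1 to 348. DPP4, a dipeptidyl peptidase of the cell surface, went from 8 to 294 counts, a ratio of 34.8 (17.4 to 81.3). The secreted lipid-binding proteins BPIFB1 and BPIFB2 had ratios of 40.5 (17.1 to 126) and 9.02 (7.92 to 10.3). COLGALT2, which adds galactose to collagen, had a ratio of 20.3 (13.4 to 32.3), and BIN1, a protein that bends membranes, 10.7 (7.70 to 15.3). SLC6A14, an amino acid transporter, stood at 7.47 (6.34 to 8.84). KRT19, a keratin of bile duct epithelium (chromosome 17, 41523617 to 41528308), had a ratio of 6.61 (5.89 to 7.43), and MATN3, a cartilage matrix protein (chromosome 2, 19992111 to 20012694), 6.73 (5.56 to 8.21). HEPACAM, a cell adhesion protein, and SPARC, a matrix-associated glycoprotein, had ratios of 6.24 (5.43 to 7.20) and 5.38 (4.74 to 6.13). These genes were higher although SOX9 itself was not.

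At the other end stood several genes of liver function. DLK1, a membrane protein of fetal liver cells (chromosome 14, 100725705 to 100738224), had 1551 counts in the control and 194 in the library labelled SOX9, which is 8.45-fold lower. The glucose transporter SLC2A2 was 7.54-fold lower, ITIH1, a heavy chain of a plasma protease inhibitor, 6.19-fold lower, and IGFBP3, a binding protein of insulin-like growth factors, 5.10-fold lower. DPYD, which degrades pyrimidines, was 5.15-fold lower, HAL, which degrades histidine, 4.86-fold, and KNG1, the precursor of bradykinin, 4.94-fold. FADS2, a fatty acid desaturase, was 4.28-fold lower and C10orf10 4.18-fold. FADS2 overlaps FADS1 and FEN1, and C10orf10 overlaps RASSF4, so that some reads of these genes could belong to their neighbours. PANK4 was 6.73-fold lower, in a row whose symbol a further row of the table carries. SOX9 lay between these extremes, at 1.27-fold lower.

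**Figure D2:**
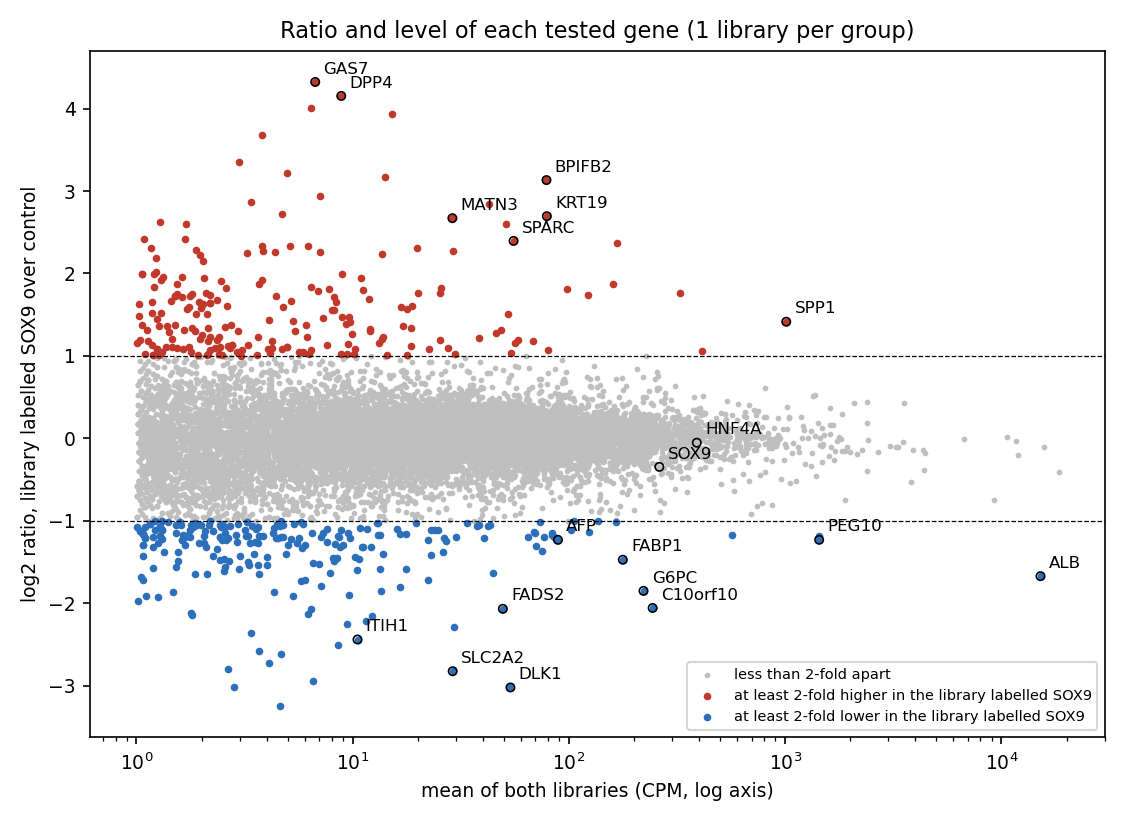
Log2 ratio of the library labelled SOX9 over the control against the mean of both libraries in CPM (log axis) for 13842 genes, with 1 library per group. Red points are the 209 genes at least 2-fold higher, blue points the 245 at least 2-fold lower, and dashed lines mark 2-fold. SOX9 lies at −0.35 and ALB, at the far right, at −1.67.

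Rows with near-identical copies gave uncertain values. Of 418 tested rows that share a symbol with a further row or lie on an alternate sequence of the genome, 78 (18.7%) were at least 2-fold apart, against 20.9 rows if they differed as often as rows with a symbol of their own at the same expression. RPS18, a ribosomal protein gene of the HLA region, showed why such rows cannot be read alone. A row of RPS18 on an alternate sequence went from 193 to 19 counts and placed it among the 12 lowest, and a further row went from 862 to 4761 counts. The 6 rows of RPS18 together held 1095 counts in the control and 4817 in the library labelled SOX9. IFNGR2, on an alternate sequence, was among the 12 highest with 20 and 219 counts, but both of its rows together had a log2 ratio of 0.81. Both rows of GGNBP2 together had a log2 ratio of −1.68, against −2.13 for the row among the 12 lowest. Without any such row, 179 genes were at least 2-fold higher in the library labelled SOX9 and 197 lower.

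Gene lists fixed before the data were examined were compared with 10000 random lists of the same size and expression. Of 46 lists with at least 3 measured genes, 11 had a median below percentile 2.5 and 15 above percentile 97.5, where 2.3 are expected outside these limits if no list stands apart. The percentiles describe these 2 libraries, and they treat genes as independent although genes of a pathway vary together.

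Genes of hepatocyte function were lower in the library labelled SOX9, which also read lower for SOX9. Of 40 measured genes of hepatocyte plasma proteins, 37 had a log2 ratio below 0, and the median was −0.40 (percentile 0, below all random lists). The set held 4 genes at least 2-fold lower and 0 at least 2-fold higher. ALB, the gene of serum albumin (chromosome 4, 73397114 to 73421412), had 373255 counts in the control and 123638 in the library labelled SOX9, a ratio of 0.313 (0.311 to 0.316). ALB took 2.27% of all counts in the control and 0.737% in the library labelled SOX9. ITIH3, a second heavy chain of the ITIH family, had a ratio of 0.442 (0.429 to 0.456). The 26 transcription factors of the liver had a median of −0.11 (percentile 0.52), with 18 below 0 and 0 at least 2-fold apart. HNF4A, a main regulator of hepatocyte genes, had a ratio of 0.963 (0.931 to 0.997). ONECUT1 and ONECUT2 had ratios of 0.609 and 0.621, and GATA6 of 1.62. Fetal liver and hepatoma markers had a median of −0.17 (percentile 1.86) over 13 genes, with DLK1, PEG10 and AFP at least 2-fold lower. AFP, the fetal counterpart of albumin, had a ratio of 0.423 (0.391 to 0.458) and PEG10, a retrotransposon-derived imprinted gene, 0.426 (0.417 to 0.434), while IGF2 stood at 1.34 (1.32 to 1.37). The median of this list lay inside the limits under 5 of 11 alternatives, at up to percentile 6.58. Acute-phase genes had a median of −0.19 (percentile 0.495) over 15 genes, with IL1RN at a ratio of 0.317 and LCN2 at 2.03.

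Most metabolic lists of the liver were lower as well in the library labelled SOX9, though glycolysis was not. Drug metabolism had a median of −0.33 (percentile 0), and 5 of its 26 measured genes were at least 2-fold lower. Among them AKR1C4 had a ratio of 0.414 (0.358 to 0.479), GSTA1 of 0.443 (0.408 to 0.480) and UGT2B4 of 0.460 (0.427 to 0.494). Bile acid synthesis and transport had a median of −0.21 (percentile 0.34) over 16 genes. CYP7A1, the rate-limiting enzyme of bile acid synthesis, had 148 and 66 counts, a ratio of 0.422 (0.311 to 0.568). Of 23 genes of the cholesterol synthesis list, 22 lay below 0 with a median of −0.30 (percentile 0), and 0 were at least 2-fold lower. HMGCS1, an early enzyme of the pathway, had a ratio of 0.589 (0.552 to 0.628), and CYP51A1, a sterol demethylase, of 0.639 (0.541 to 0.753). Fatty acid synthesis had a median of −0.25 over 18 genes and fatty acid oxidation with ketogenesis −0.35 over 16 genes, both at percentile 0. FABP1, the liver fatty acid binding protein, had a ratio of 0.359 (0.338 to 0.380), and AGPAT2, which acylates lysophosphatidic acid, of 1.93 (1.68 to 2.22). Hypoxia genes had a median of −0.22 (percentile 0.02) over 21 genes, of which 16 lay below 0 and 5 above, with EPO at 0.516 (0.387 to 0.683) and SLC2A1, a glucose transporter, at 1.99 (1.90 to 2.09). Gluconeogenesis and the urea cycle had a median of −0.17 at percentile 2.69, just inside the limit, and under 10 of 11 alternatives it lay below 2.5. In this list G6PC, which releases glucose, had a ratio of 0.276 (0.261 to 0.292). Glycolysis had a median of −0.02 (percentile 36.7), with SLC2A1 a member here as well.

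The cartilage and biliary lists read higher in the library labelled SOX9, against the direction of SOX9 itself. Cartilage matrix genes had a median of 0.41 (percentile 99.9) over 7 of 20 genes, of which 5 lay above 0 and 2 below. MATN3 was the member at least 2-fold higher, COL9A3 had a ratio of 1.51 (1.44 to 1.57) and C2orf82 of 1.67 (1.59 to 1.75). COL2A1, the main collagen of cartilage, had 47 and 69 counts, and its ratio of 1.39 (0.945 to 2.06) was not distinguishable from 1 at this depth. The median of the list is the value of COL2A1. With a minimum mean of 5 CPM, which COL2A1 does not reach, the list median was 0.59 (percentile 100). Biliary and progenitor markers had a median of 0.19 (percentile 98.6) over 13 genes, of which 7 lay above 0 and 6 below. KRT19, CD24 and SPP1 were at least 2-fold higher and TM4SF4 at least 2-fold lower. SPP1, the gene of osteopontin, went from 8920 to 25133 counts, a ratio of 2.67 (2.60 to 2.73). The SOX family had a median of 0.09 (percentile 78.7) over 6 genes, of which 3 lay above 0 and 3 below. SOX4 had a ratio of 2.59 (2.07 to 3.25), SOX6 of 2.31 (1.81 to 2.97) and SOX12 of 0.832 (0.793 to 0.873).

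In the main analysis the lists of TGF-beta targets, WNT targets and the NOTCH pathway also lay above their random lists in the library labelled SOX9. YAP targets and WNT receptors and ligands did not. The list of TGF-beta targets had a median of 0.32 (percentile 100) over 18 genes, of which 13 lay above 0 and 5 below. THBS1 had a ratio of 2.31 (2.09 to 2.55) and ID1 of 1.79 (1.70 to 1.88). The members ID1, ID3 and SMAD6 are also targets of BMP signals, so the median of this list does not single out TGF-beta. The NOTCH pathway had a median of 0.21 (percentile 99.0) over 14 genes, of which 8 lay above 0 and 6 below. Its target HEY1 had a ratio of 2.42 (1.97 to 2.99), the receptor NOTCH1 2.31 (1.88 to 2.86) and the ligand JAG1 1.65 (1.56 to 1.74). Targets of WNT had a median of 0.14 (percentile 98.4) over 15 genes, with TNFRSF19 at 1.68 and RNF43 at 1.57. The NOTCH median lay inside the limits under 2 of 11 alternatives, at percentile 95.5 with no minimum level, and the WNT target median under 1, at 96.6 with FPKM. WNT receptors and ligands stood at percentile 96.0, with a median of 0.13, with no minimum level, so their contrast with NOTCH depends on that level. YAP targets stood at percentile 6.5, with a median of −0.09, with a minimum mean of 5 CPM. Mesenchymal genes had a median of 0.30 (percentile 99.7) over 12 genes, but the sign turned to −0.30 with a minimum mean of 5 CPM, and with FPKM the median lay at percentile 92.6. SPARC was higher and CDH2, the gene of N-cadherin, lower, at a ratio of 0.431 (0.393 to 0.473). Stem cell markers had a median of 0.18 (percentile 99.1) over 15 genes, which include KRT19 and CD24, while CD47 had a ratio of 0.473 (0.323 to 0.684).

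Genes of the cell cycle were slightly higher in the library labelled SOX9. Of 30 genes of S phase, 27 lay above 0, with a median of 0.25 (percentile 100) and 0 at least 2-fold apart. CCNE1, the gene of cyclin E, had a ratio of 1.45 (1.27 to 1.65) and RRM2, a subunit of ribonucleotide reductase, 1.33 (1.25 to 1.42). Of 30 genes of G2 and M phase, 24 lay above 0, with a median of 0.14 (percentile 99.8), and MKI67 had a ratio of 1.28 (1.24 to 1.32). Cyclins and CDK inhibitors had a median of 0.17 (percentile 98.6) over 15 genes, with CCND2 at 3.52 (2.92 to 4.27) and CDKN1A at 1.55 (1.47 to 1.63). MYC had a ratio of 1.14 (1.07 to 1.20). Targets of p53 had a median of 0.17 (percentile 99.9), with 21 of 23 genes above 0 and FAS at 1.93 (1.66 to 2.25). Several stress lists, but not hypoxia, had medians above 0 in this library, in which SOX9 itself read lower. Of 20 NRF2 targets 19 lay above 0, with a median of 0.34 (percentile 100). AKR1B10, a reductase, had a ratio of 2.09 (2.02 to 2.17) and OSGIN1, an oxidative stress response gene, 1.55 (1.39 to 1.74). Heat shock genes had a median of 0.20 (percentile 99.9) over 14 genes and immediate early genes 0.15 (percentile 99.3) over 24. All 6 measured metallothioneins lay above 0, with a median of 0.39 (percentile 100) and MT2A at 1.42 (1.36 to 1.49).

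**Figure D3:**
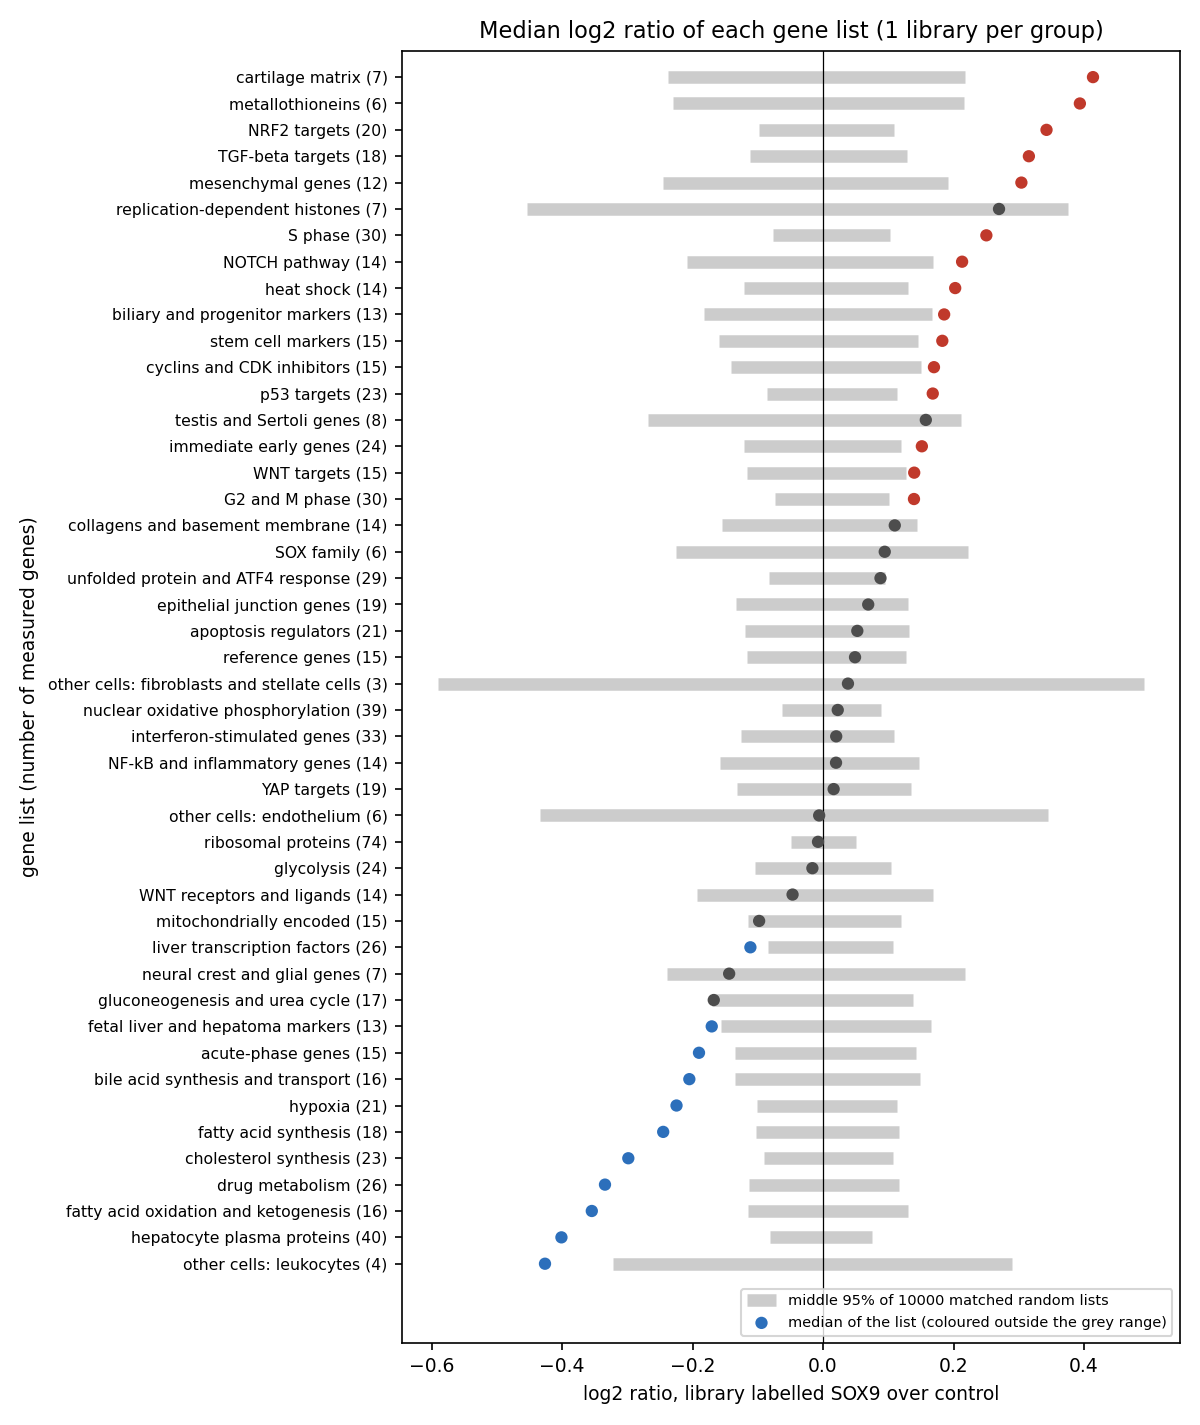
Median log2 ratio of 46 gene lists (points), library labelled SOX9 over control, with the middle 95% of 10000 matched random lists (grey bars) and the number of measured genes in brackets. Red points, from cartilage matrix at 0.41 down to G2 and M phase at 0.14, lie above their bars, and blue points, down to leukocyte markers at −0.43, lie below theirs.

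Other lists lay inside their random range in the main analysis. Ribosomal proteins had a median of −0.01 (percentile 29.5) over 74 genes, nuclear genes of oxidative phosphorylation 0.02 (percentile 58.8) over 39, and mitochondrially encoded genes −0.10 (percentile 5.58) over 15. Mitochondrial genes took 6.09% of counts in the control and 5.99% in the library labelled SOX9. Interferon-stimulated genes had a median of 0.02 (percentile 64.9) over 33 genes, and the same median with IFI27 at its bound. IFI27 had 0 counts in the control and 37 in the library labelled SOX9, at least 11.7-fold higher against a floor of 3 counts in the control if the 37 are taken as exact (9.03-fold as the exact 95% lower bound), and a further row carries its symbol. YAP targets (0.02, percentile 54.8), WNT receptors and ligands (−0.05, percentile 31.5), apoptosis regulators (0.05, percentile 77.3) and inflammatory genes (0.02, percentile 59.8) had medians near 0. Epithelial junction genes stood at 0.07 (percentile 85.2), and the unfolded protein and ATF4 response at 0.09 (percentile 96.4). Collagens and basement membrane genes stood at 0.11 (percentile 94.2), replication-dependent histones at 0.27 (percentile 93.4), testis and Sertoli genes at 0.16 (percentile 93.2), and neural crest and glial genes at −0.14 (percentile 9.21). Of these, epithelial junction genes lay above percentile 97.5 under 2 of 11 alternatives (up to 100), collagens under 1 of 11 (100) and histones under 3 of 10 (97.6 to 99.6). Of the intestinal and pancreatic list 2 genes were measured, MUC13 with a ratio of 5.25 (4.25 to 6.54) and VIL1 with 0.969. Reference genes had a median of 0.05 (percentile 77.7) over 15 genes. Among them ACTB had a ratio of 1.29 (1.27 to 1.31) and HPRT1 of 0.623 (0.563 to 0.689).

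Markers of cells that a HepG2 culture should lack were mostly low. PTPRC, CD68, COL1A1 and COL1A2 had 0 counts in both libraries. Summed endothelial markers were 36.4 CPM in the control and 41.0 CPM in the library labelled SOX9, and the endothelial median was −0.01 (percentile 57.0) over 6 genes. Summed fibroblast and stellate cell markers were 27.5 and 25.8 CPM, with a median of 0.04 (percentile 61.1) over 3 genes. Other epithelial markers summed to 6.99 and 6.44 CPM, and PAX8 and SYP were measured. Leukocyte markers had a median of −0.43 (percentile 0.81) over 4 genes, which turned to 0.11 with no minimum level. Of these genes LYZ, the gene of lysozyme, had 1790 CPM in the control and 1602 CPM in the library labelled SOX9, and CD14 had 12.1 and 4.10 CPM.

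The authors' deposited table gave its own comparison, with a p-value for 23533 rows. Of the rows in the authors' deposited table, 151 had an adjusted p under 0.05, of which 100 were higher and 51 lower in the library labelled SOX9. At least 2-fold apart here were 133 of the 151. For SOX9 the authors' deposited table gave a log2 fold change of −0.35 and an adjusted p of 1. For ALB the authors' deposited table gave a log2 fold change of −1.67 and an adjusted p of 0.0155. All 23533 p-values of the authors' deposited table were equal, within 1e-06, to those of the edgeR exact test with a preset dispersion of 0.04. With 1 library per group the spread between cultures cannot be estimated, so these p-values rest on that assumed value and say nothing of replicate cultures.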

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

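Summing rows with the same symbol and TMM scaling without the 50 most abundant genes were chosen after the data were seen, the other alternatives before. The SOX9 log2 ratio lay between −0.36 and −0.29 under all 11 alternatives, below 0 in each. The number of genes at least 2-fold higher in the library labelled SOX9 was 324 with no minimum level, 86 with a minimum mean of 5 CPM and 103 with a pseudocount of 2 CPM, against 209. The number at least 2-fold lower was 352 with no minimum level, 106 with a minimum mean of 5 CPM and 102 with a pseudocount of 2 CPM, against 245. A minimum level tests fewer genes and a larger pseudocount shrinks the ratios of low genes, by construction. With FPKM, 308 genes were higher and 350 lower, of which 102 and 152 were among the 209 and 245. The library sizes behind the FPKM values equal those of the DESeq2 size factors, which gave 223 and 233 genes. Of these, 209 and 233 were among the 209 and 245, so the lower overlap with FPKM comes from its minimum level and pseudocount. All other values of both numbers stayed within 1.5 times. Genes higher made up between 44.4% and 51.3% of those at least 2-fold apart. Of the lists outside percentiles 2.5 to 97.5, medians of 2 turned their sign. Mesenchymal genes stood at −0.30 with a minimum mean of 5 CPM, and leukocyte markers at 0.11 with no minimum level, where the set of measured members differs. Some medians of lists inside these limits, near 0, crossed it as well. Of the other list medians under each alternative, 483 stayed within 0.1 of the main log2 value and 18 moved further. Values of rows of named genes stayed within the counting interval or within 0.1 in 2058 comparisons and moved further in 28. Rows that the summing of same-named rows merges into another are not among these, and RPS18 turned from −2.95 for the row among the 12 lowest to 2.05 for its rows together. Depth limits genes near the minimum level, where few counts stand behind a ratio. No paired analysis was possible because each group held 1 library.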

Other observations

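All tests in this part were chosen after the results were seen. The neighbour count was prompted by the presence of BPIFB1 and BPIFB2 among the highest genes, and genes named here for their position were chosen after their values were seen.

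Of 450 tested lincRNA genes 6 were at least 2-fold higher and 19 lower in the library labelled SOX9, and of 482 antisense genes 6 were higher and 13 lower. Of 351 processed pseudogenes 1 was higher and 7 lower.

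Genes at least 2-fold lower in the library labelled SOX9, in which SOX9 itself read lower, included several sets of neighbours. Neighbours are genes next to each other among tested protein-coding genes with a symbol of their own, so other genes can lie between them. These were ALB with AFP on chromosome 4, ITIH1 with ITIH3 on chromosome 3, IGFBP1 with IGFBP3 on chromosome 7, CETP with NLRC5 on chromosome 16, FAM171A2 with ITGA2B on chromosome 17, C10orf10 with ZNF22 on chromosome 10, and SLC25A27 with MEP1A on chromosome 6. On the X chromosome MAGEA3, CSAG1, MAGEA12 and MAGEA6 formed a run. These are cancer-testis antigen genes at low levels, and CSAG1 had 31 counts in the control and 2 in the library labelled SOX9, a ratio of 0.0611 (0.00708 to 0.240). ZNF22, a zinc finger gene, had 108 and 12 counts, and IGFBP1, a binding protein of insulin-like growth factors, 32156 and 14882. Among higher genes the neighbours were KRT15 with KRT19, BPIFB2 with BPIFB1, SLMO1 with SPIRE1 and SH2D4A with CSGALNACT1.

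Of 11450 protein-coding genes with a symbol of their own, the 135 at least 2-fold lower formed 10 adjacent pairs, where 10000 shuffles of the ratios within chromosomes gave 1.52 on average and at most 4 in 97.5% of cases. The 157 at least 2-fold higher formed 4 pairs, within the shuffled range, for which 97.5% of shuffles gave at most 6. Reads shared between neighbouring copies of 1 gene family remain open as a cause for pairs within a family. The count without such families cannot settle this, because it also drops related genes that may be regulated together. Without runs that hold genes with the same first 3 letters, or ALB with AFP, 4 pairs remained, where shuffles treated alike gave 1.46 on average and at most 4 in 97.5% of cases. Regional regulation of neighbouring genes that read lower may also underlie part of the 10 pairs, as a hypothesis, and 1 library per group cannot separate it from a difference between sublines that arose in culture.

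SOX9 was not higher in the library labelled SOX9. Too few reads are not the reason, since the upper bound of the ratio of the library labelled SOX9 over the control was 0.820. An exchange of labels remains open: the control read 1.27 times the library labelled SOX9, and the upper bound of 1.33 lies under a doubling but covers counting error only, not a difference in the cells' own SOX9 between sublines. Whether reads of an introduced SOX9 were counted in the SOX9 row cannot be told apart from its absence, because 0 columns of the table hold coverage per base or exon. Whether an introduced SOX9 acts in the library labelled SOX9 stays open too, since of 5 lists tied to SOX9 with a percentile the cartilage and biliary lists, 2 in all, lay above 97.5, while the SOX family stood at percentile 78.7, testis and Sertoli genes at 93.2 and neural crest and glial genes at 9.21.

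Genes of hepatocyte plasma proteins were lower in the library labelled SOX9, with a median log2 ratio of −0.40. A lower share of hepatocyte-like cells would be expected to lower the liver transcription factors alike, but 4 of 26 lay at or below that median. That list was itself low, with a median of −0.11 (percentile 0.52) and 18 of 26 below 0, so a change in cell composition is not settled. GC content and gene length are argued against, as the only cause, by percentile 0 among random lists matched on expression, length and GC content. A GC value was at hand for 100% of members. The matching used coarse classes of length and GC content, so a graded effect within a class is not excluded. An effect of an introduced SOX9, if present, a change in cell composition and a chance difference between sublines all remain open. Each group held 1 library.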
